A study of Macaca fascicularis with 23 samples.

How the data were processed

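RNA from the liver of cynomolgus monkeys (Macaca fascicularis) given vehicle or ciprofibrate, a fibrate drug that activates the nuclear receptor PPAR-alpha, was measured on 23 arrays, 1 per animal. Per the labels' protocols, tissue from the right lateral lobe was frozen, total RNA was isolated with TRIzol, and biotin-labelled cRNA was prepared from it. The probes were designed against human transcripts, so monkey sequence differences can change a probe set's signal. Values are compared within a probe set only, so differences that all animals share act alike in all groups of a contrast. Differences between single animals need not, and which probes match monkey transcripts was not checked.

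The deposited values are probe set intensity values on a linear scale that the authors computed with MAS5, per the submitters' processing notes. The MAS5 version and settings were not given in the sources used here. The mean of each array after trimming 2% at each end lay between 150.065 and 150.08, so all arrays had been scaled to a common target and no further scaling was applied. Array medians ran from 55 to 71.6. Detection calls were not used here.

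Of 12625 probe sets, 67 control probe sets were left out of the tests. Values were converted to log2 after a pseudocount of 16. Among the remaining 12558 probe sets, those with a mean log2 value at or above the 40th percentile were tested, which left 7535 with a mean of at least 5.80, an intensity of 39.7. Of all probe sets, 10961 named 1 gene, 545 named several and 1119 named none. A gene was represented by the tested probe set with the highest mean among those that named it alone, which gave 5462 genes.

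Arrays were grouped by dose and day from their labels into 7 groups. A means model for the 7 groups was fitted to all arrays together with limma 3.58.1 in R 4.3.3, so that groups of 2, 3 and 4 animals shared 1 estimate of spread for each probe set (16 residual and 6.63 prior degrees of freedom). Moderated statistics used an intensity trend. All tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the 7535 probe sets, and a probe set was called at an adjusted p under 0.05. Contrasts compared each dose with vehicle of the same day, the slope over the 5 dose steps at 15 days (vehicle included, equally spaced), the 15-day with the 4-day effect of 400 mg/kg/day, vehicle at 15 with vehicle at 4 days, and 400 with 3 and with 150 mg/kg/day. The standard error (SE) of each contrast comes from that fit, while the standard deviation (SD) of intensities is that of a group's arrays. The number of arrays per group limits the precision.

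Gene lists for 35 pathways and cell types were fixed before the values were seen. They held 909 genes, of which 598 were represented, and 34 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists. Each test was repeated with a correlation estimated from the data and with fry. Members were counted as called over all probe sets tested and, separately, adjusted over the list alone.

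The genes to be named were chosen by a rule fixed beforehand. For 400 mg/kg/day at 15 days these were the 10 called genes with the largest rise and the 10 with the largest fall whose treated and vehicle arrays did not overlap. The 5 largest each way were taken for 4 days, for the slope, for the difference between days and for 400 against 3 mg/kg/day, and the 3 largest each way for the lower doses, with up to 4 members with the smallest p for each list discussed. Genes of PPAR-alpha signalling, lipoproteins and early response and the control genes ACTB and GAPDH were named wherever measured. Some genes of this rule are not reported here. CYP4A11 and APOA2 were not analysed here, and EHHADH and CYP7A1 fell below the intensity filter.

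The fit was tested on simulated data built on the real probe sets. For 400 mg/kg/day against vehicle at 15 days it recovered 2 of 67 probe sets changed by 0.5 on the log2 scale, 16 of 67 changed by 1 and 57 of 66 changed by 2, with 4 false calls among 7335 unchanged probe sets. For the 4-day comparison 0 of 67, 10 of 67 and 40 of 66 were recovered, with 4 false calls. For 400 against 3 mg/kg/day these were 1 of 67, 23 of 67 and 61 of 66, with 3 false calls. The list test called a list shifted by 0.5 and 0 others. Genes varied independently in that simulation, so it cannot show how often correlation between genes gives false list calls.

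Alternatives covered the pseudocount, the filter, quantile and median scaling between arrays, the variance trend and robust options, array weights, a block for the replicate number, separate fits, other dose scores, the probe set summary and correlation behind the list tests, and leaving out each animal in turn. Labels were also regrouped in every other way, or in a random sample of ways for the slope, to see how many calls chance groupings gave. The ratio of 5' to 3' probe sets of ACTB and GAPDH, an index of RNA integrity and labelling, was checked by day with exact permutation tests.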

Results

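Liver gene expression was measured in 23 monkeys, each on a human gene array, as probe set intensity. After 4 days there were 2 vehicle animals and 2 given ciprofibrate at 400 mg/kg/day. After 15 days there were 3 vehicle animals and 4 animals at each of 3, 30, 150 and 400 mg/kg/day. The number of arrays limits the precision, most of all at 4 days. Arrays had a mean correlation to the rest of their own group between 0.846 and 0.921. The ratio of 5' to 3' ACTB probe sets was higher at 4 days, 0.992 ± 0.190 (SD, n = 4), than at 15 days, 0.657 ± 0.13 (SD, n = 19; exact permutation p = 0.00124, 0.00248 after adjustment over 2 ratios). For GAPDH this ratio was 1.02 ± 0.10 and 1.17 ± 0.22 (exact permutation p = 0.307).

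The comparison of 400 mg/kg/day with vehicle at 15 days asks what the highest dose did to the liver after prolonged dosing. The lists of mitochondrial fatty acid oxidation and fatty acid synthesis were higher, and CYP2E1 and some genes of plasma proteins and complement fell. FADS2, a fatty acid desaturase, rose by 4.22 ± 0.64 (SE) on the log2 scale (adjusted p = 0.000403), from an intensity of 37.0 ± 14.5 (SD, n = 3) to 971.5 ± 218 (SD, n = 4). The vehicle intensity lay around the filter's limit of 39.7 and was not shown to exceed background, so the size of the rise depends on the pseudocount. FABP1, the liver fatty acid binding protein, rose 9.86-fold (3.30 ± 0.53, adjusted p = 0.000928). CYP2E1, an enzyme that oxidises ethanol and other small molecules, fell by 3.56 ± 0.49 on the log2 scale (adjusted p = 0.000161), from 13669 ± 1635 (SD, n = 3) to 1479 ± 859 (SD, n = 4). Without 400 mg/kg/day replicate 1, the lowest animal, CYP2E1 fell by 2.85 and was still called. In all, 161 of 7535 probe sets were called, of which 95 rose, for 66 genes, and 66 fell, for 51 genes. In the same comparison 940 had an unadjusted p under 0.05 where 377 were expected by chance.

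Among the other largest rises, AKR1B10, an aldo-keto reductase, rose by 3.61 ± 0.40 (adjusted p = 1.12e-05), from a vehicle intensity of 33.4 ± 9.82 (SD, n = 3), also not shown to exceed background. SCD, which makes monounsaturated fatty acids, rose 8.63-fold (3.11 ± 0.59, adjusted p = 0.00415). NQO1, a quinone reductase, rose 5.49-fold (2.46 ± 0.25, adjusted p = 5.45e-06). The tight junction gene CLDN10, with a similarly low vehicle intensity of 29.8 ± 18.3 (SD, n = 3), rose by 2.45 ± 0.53 (adjusted p = 0.0106). The carnitine carrier SLC22A5 rose by 1.98 ± 0.39, the retinal-oxidising ALDH1A1 by 1.96 ± 0.25, the chemokine CCL15 by 1.95 ± 0.36 and the fatty acid elongase ELOVL5 by 1.63 ± 0.26. Among the other largest falls were those of the protease inhibitor PZP (-2.64 ± 0.51), the fibrinogen-like FGL1 (-2.62 ± 0.53), the secreted phosphoprotein SPP2 (-2.45 ± 0.37) and CFHR4, related to complement factor H (-2.04 ± 0.51). HGFAC, which activates hepatocyte growth factor, changed by -2.12 ± 0.21 (adjusted p = 3.95e-06) and IGFALS, which holds IGF in the circulation, by -2.10 ± 0.33. Falls were also called for PCDH9, a protocadherin (-2.18 ± 0.56), for the metalloproteinase inhibitor TIMP1 (-1.81 ± 0.42) and for the transcription factor subunit NFYA (-1.77 ± 0.42). In treated animals SPP2, PCDH9, TIMP1 and NFYA had mean intensities of 40.6, 25.5, 43.8 and 31.1, around the filter's limit of 39.7, so the sizes of these falls are not exact either.

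**Figure D1:**
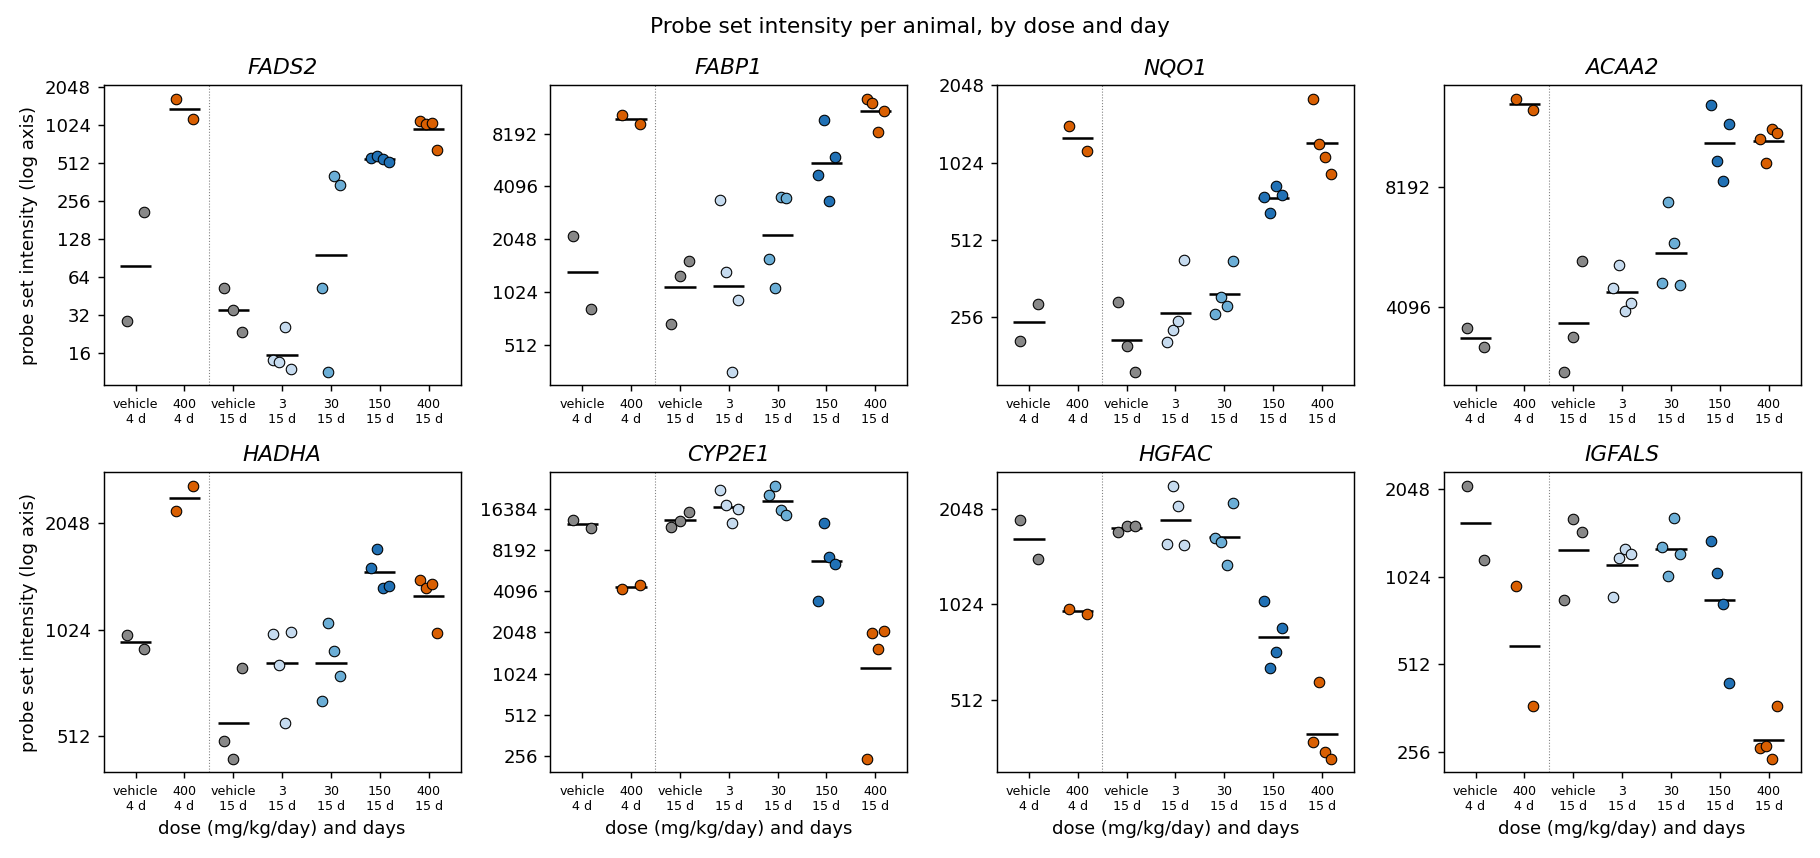
Probe set intensity on a log axis for 8 genes, by dose in mg/kg/day and day. Each point is 1 animal and each bar the geometric mean of its group. Arithmetic means, which differ from the bars, were 37.0 for FADS2 in 15-day vehicle animals and 971.5 at 400 mg/kg/day, and 13669 and 1479 for CYP2E1.

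Mitochondrial fatty acid oxidation was the list with the smallest p: 7 of 17 measured genes rose, 0 fell and 10 were not called (median log2 change 0.86, adjusted p = 1.2e-18, 0.00558 with an estimated correlation). When adjusted over the list alone, 14 rose. ACAA2, a thiolase, rose by 1.51 ± 0.20, the trifunctional protein subunits HADHB by 1.61 ± 0.29 and HADHA by 1.16 ± 0.22 (adjusted p = 0.00366), and the electron transfer flavoprotein ETFA by 1.11 ± 0.18. Among 15 known PPAR-alpha targets, 4 rose, 0 fell and 11 were not called (adjusted p = 5.5e-10, 0.00169 with an estimated correlation). SLC25A20, the acylcarnitine carrier, rose by 1.07 ± 0.26, and 7 rose when adjusted over the list alone. This list shares genes with others, such as HADHA and SLC25A20 with mitochondrial fatty acid oxidation and FADS2 with fatty acid synthesis. The calls of these lists are thus not independent. Of 14 fatty acid and triglyceride synthesis genes, 4 rose and 10 were not called (median 0.66, adjusted p = 3.48e-08, 0.000387 with an estimated correlation). The malic enzyme ME1 rose by 1.25 ± 0.28, and 7 rose when adjusted over the list alone. The proteasome list had 6 of 33 genes rising and 27 not called (median 0.38, adjusted p = 5.5e-10, 0.0139 with an estimated correlation). PSMB3 rose by 1.06 ± 0.20, PSMB6 by 0.73 ± 0.15 and PSMB5 by 0.69 ± 0.14, and 11 rose and 1 fell when adjusted over the list alone. In oxidative phosphorylation 3 of 53 genes rose and 50 were not called (median 0.22, adjusted p = 0.000264, but adjusted p = 0.15 with an estimated correlation). The cytochrome oxidase subunits COX6A1 and COX5A rose by 0.69 ± 0.13 and 1.05 ± 0.21 and the ATP synthase subunit ATP5PF by 1.38 ± 0.36, from a low vehicle intensity of 17.2, and 5 rose when adjusted over the list alone.

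In the oxidative stress and metal response list, NQO1, the redox protein thioredoxin (TXN, 1.35 ± 0.19) and the lipid peroxide reductase GPX4 (0.74 ± 0.18) rose and 22 of 25 genes were not called, with a median of 0.02 and a mean of 0.19 (adjusted p = 0.0179, but adjusted p = 0.143 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell. Xenobiotic metabolism had 4 genes rising, including CYP3A4 at 1.31 ± 0.26, CYP2E1 falling and 21 of 26 not called (median 0.21, adjusted p = 0.0236, but adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, 6 rose and 1 fell. The call of the oxidative stress list ended under quantile normalization and without 15-day vehicle replicate 2, 15-day vehicle replicate 3 or 400 mg/kg/day replicate 3. That of xenobiotic metabolism ended under quantile normalization and without 15-day vehicle replicate 3 or 400 mg/kg/day replicate 1.

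Among 20 complement genes 3 fell and 17 were not called (median -0.36, adjusted p = 3.4e-05, but adjusted p = 0.0933 with an estimated correlation), and 6 fell when adjusted over the list alone. Those called were CFB of the alternative pathway (-0.86 ± 0.15) and the terminal components C8B (-1.37 ± 0.25) and C8A (-1.12 ± 0.24). For acute phase and other plasma proteins 6 of 27 fell and 21 were not called (median -0.19, adjusted p = 0.00321, but adjusted p = 0.143 with an estimated correlation). They included ITIH2, a hyaluronan-binding plasma protein (-1.21 ± 0.23), and angiotensinogen, AGT (-1.05 ± 0.20). Adjusted over the list alone, 8 fell. In the coagulation and fibrinolysis list 3 of 28 genes fell and 25 were not called (median -0.21, adjusted p = 0.00436, but adjusted p = 0.167 with an estimated correlation). They were the clotting factors F12 (-1.09 ± 0.22) and F7 (-0.72 ± 0.16) and prekallikrein, KLKB1 (-1.01 ± 0.25), and 3 fell when adjusted over the list alone. Of the 19 immediate early genes, 3 fell and 16 were not called (median -0.41, adjusted p = 0.000197, 0.0139 with an estimated correlation). They were the mRNA-destabilising ZFP36 (-0.98 ± 0.19), the phosphatase DUSP1 (-1.68 ± 0.36) and the transcription factor CEBPB (-0.89 ± 0.22). Adjusted over the list alone, 5 fell. At 15 days the lower doses had medians of similar size for this list, against the same vehicle animals. The shifts at these doses are thus not independent of each other.

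Among the lists of markers of other liver cells, 3 were lower at this dose. Endothelial markers had 0 of 9 genes called (median -0.63, list adjusted p = 0.00778, 0.0358 with an estimated correlation), and 0 were called when adjusted over the list alone. FCN3 differed from vehicle by -0.70 and PECAM1 by -0.85, though its other probe sets differed by -0.28 and 0.12. Stellate cell and fibroblast markers had TIMP1 falling and 11 of 12 not called (median -0.45, adjusted p = 0.00436, but adjusted p = 0.107 with an estimated correlation), with 2 falling when adjusted over the list alone. Of 8 Kupffer cell and macrophage markers 0 were called (median -0.36, adjusted p = 0.0134, but adjusted p = 0.0949 with an estimated correlation), and 3 fell when adjusted over the list alone. CD5L differed from vehicle by -1.32 and CD14 by -0.68. The calls of the endothelial and macrophage lists ended without 15-day vehicle replicate 3 (adjusted p = 0.111 and 0.0887).

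The other 20 lists tested were not called. Peroxisomal fatty acid oxidation had 1 of 8 genes rising, HSD17B4 (0.90 ± 0.23), with a list adjusted p of 0.0673, and peroxisome assembly had an adjusted p of 0.427. For cholesterol synthesis NSDHL rose by 1.05 ± 0.21 among 16 genes (list adjusted p = 0.24), and among 10 bile acid genes the fatty acid transporter SLC27A2 rose by 1.28 ± 0.33 (list adjusted p = 0.122). Hepatocyte markers had CYP2E1 falling and 8 of 9 not called, with a median of 0.00 and a mean of -0.41 (adjusted p = 0.122), and in the ER stress list HERPUD1 rose by 1.16 ± 0.30 (list adjusted p = 0.203). The remaining list adjusted p values were 0.0621 for cell cycle, 0.147 for hepatocyte transcription factors, 0.465 for B and plasma cell markers, 0.494 for ribosomal proteins, 0.583 for apolipoproteins, 0.758 for the urea cycle and 0.788 for red cell markers. They were 0.881 each for cholangiocyte and neutrophil markers, DNA damage response, apoptosis, the TCA cycle and glycolysis, the last pair of lists having medians of -0.04 and -0.09 with means of 0.03 and 0.02, and 0.995 for T and NK cell markers. The receptor gene PPARA differed from vehicle by -0.41 ± 0.20 (adjusted p = 0.408), CPT1A, which starts mitochondrial fatty acid import, by 0.48 ± 0.39, the lipid droplet gene PLIN2 by 0.93 ± 0.42, PDK4 by 0.31 and catalase (CAT) by 0.45 ± 0.36, none of them called. Nor were APOA1 (-0.42 ± 0.19), APOC3 (-0.02), MYC (-0.20), JUN (-0.41), NFKBIA (-0.10) and the control genes ACTB (0.52 ± 0.21) and GAPDH (0.00 ± 0.21) called. In the 7 fits that each left out 1 animal, PCDH9 lost its call in all 7, ATP5PF, CEBPB, HERPUD1 and SLC27A2 in 6 each, and KLKB1 in 5. CFHR4, GPX4, HSD17B4, SLC25A20 and TIMP1 lost theirs in 4 each, F7 and NFYA in 3 and ME1 in 2. CLDN10, SLC22A5, FGL1, PSMB5, PSMB6, COX5A, C8A, F12, DUSP1 and NSDHL lost theirs in 1 each. Other alternatives ended the calls of ATP5PF and CEBPB in 6 fits each and of HSD17B4, KLKB1 and SLC27A2 in 5. Those of CFHR4, F7, GPX4 and HERPUD1 ended in 4, of PCDH9 and SLC25A20 in 3 and of NFYA in 2. CLDN10, COX5A, DUSP1, F12 and TIMP1 lost theirs in 1 each. Of the genes called in every fit without 1 animal, CYP3A4 lost its call in 2 such alternatives (adjusted p up to 0.0643) and COX6A1 in 1 (adjusted p = 0.087). The 161 calls came down to 93 without 15-day vehicle replicate 1 and 94 without 400 mg/kg/day replicate 1, and up to 252 with array weights. With each array scaled to the same median 109 rose and 40 fell. The ratio of 5' to 3' ACTB probe sets was 0.574 ± 0.033 (SD, n = 3) in vehicle and 0.681 ± 0.126 (SD, n = 4) in treated animals.

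**Figure D2:**
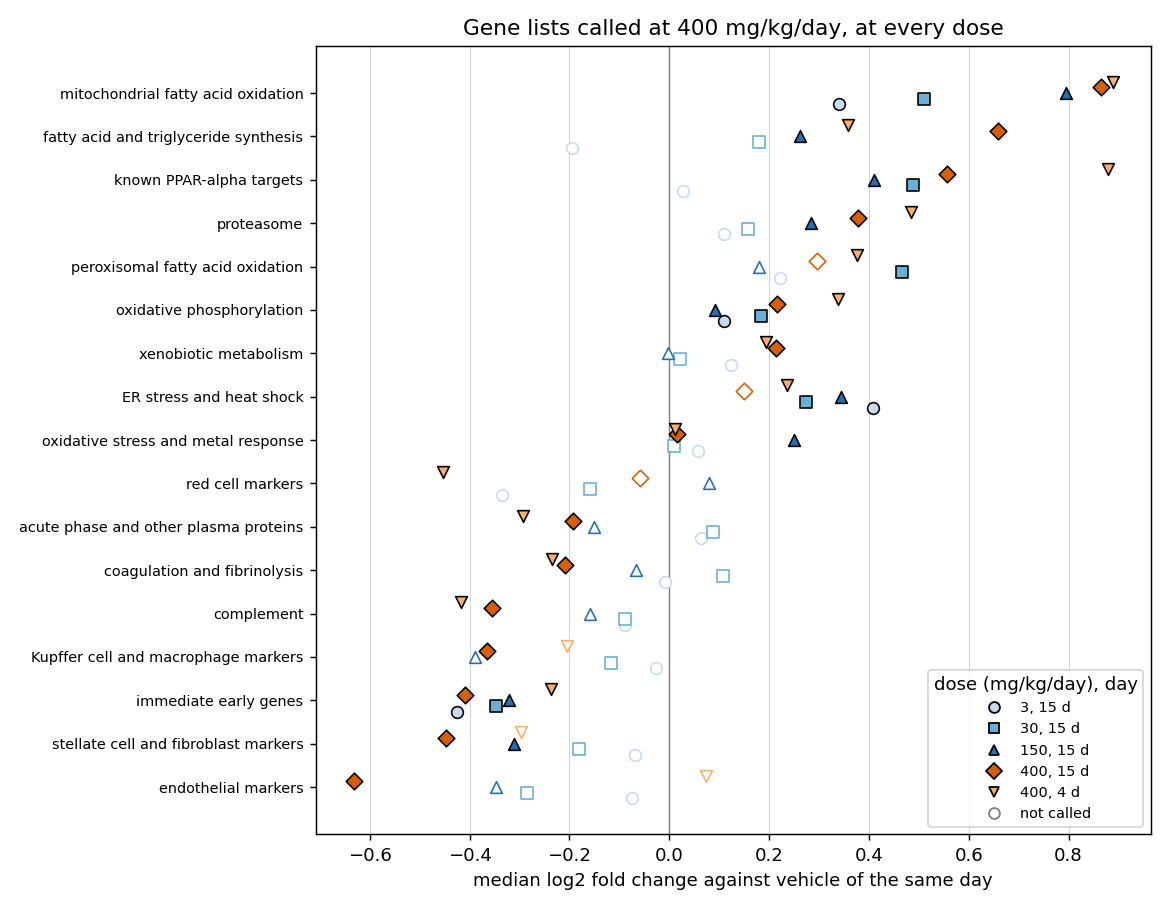
Median log2 fold change against vehicle of the same day for each gene list called at 400 mg/kg/day at 4 or 15 days, at every dose. Filled symbols are lists called with the preset correlation and open symbols lists not called. Mitochondrial fatty acid oxidation had medians of 0.34, 0.51, 0.79 and 0.86 from 3 to 400 mg/kg/day at 15 days.

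In the 15-day animals on 150 mg/kg/day the list of mitochondrial fatty acid oxidation was higher. FADS2 rose by 3.46 ± 0.64 (adjusted p = 0.00877), the metal-binding metallothionein MT1G rose by 2.86 ± 0.50 (adjusted p = 0.00632) and FABP1 by 2.33 ± 0.53 (adjusted p = 0.0394). The largest falls were those of the exosome subunit EXOSC2 (-2.32 ± 0.35), TIMP1 (-2.03 ± 0.42) and the mitochondrial thymidine kinase TK2 (-1.91 ± 0.42). Their mean intensities in treated animals were 49.4, 35.3 and 30.4, around the filter's limit of 39.7 as for FADS2 in vehicle animals, so these sizes and their order are not exact. Mitochondrial fatty acid oxidation had 6 of 17 genes rising and 11 not called (adjusted p = 2.27e-18, 0.014 with an estimated correlation). HADHB stood at 1.67 ± 0.29, ACADS, which starts the breakdown of short chains, at 1.45 ± 0.28 and HADHA at 1.38 ± 0.22, and 13 rose when adjusted over the list alone. PPAR-alpha targets had 5 of 15 rising and 10 not called (adjusted p = 1.54e-06, 0.014 with an estimated correlation). The peroxisomal thiolase ACAA1 rose by 1.03 ± 0.17, and 6 rose when adjusted over the list alone. The proteasome had 2 of 33 rising, PSMA3 and PSMB6 (adjusted p = 1.17e-06, 0.0414 with an estimated correlation; 6 adjusted over the list alone). Oxidative stress and metal response had 2 of 25 rising, NQO1 and MT1G (median 0.25, adjusted p = 0.000592, 0.0414 with an estimated correlation; 4 rose and 1 fell adjusted over the list alone). Of 14 fatty acid synthesis genes FADS2 alone rose (adjusted p = 0.00305, 0.0172 with an estimated correlation), also when adjusted over the list alone. Immediate early genes had 0 of 19 called and a median of -0.32 (adjusted p = 0.000107, 0.0151 with an estimated correlation), and 8 fell when adjusted over the list alone.

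Another 4 lists were called at 150 mg/kg/day with the preset correlation only. These were ER stress (median 0.34, 0 of 25 genes called, adjusted p = 0.00679, and adjusted p = 0.195 with an estimated correlation) and the urea cycle (median 0.19, MAT1A rose by 0.79 ± 0.17, adjusted p = 0.00773, and adjusted p = 0.195 with an estimated correlation). They also included stellate cell markers (median -0.31, TIMP1 fell, adjusted p = 0.0236, and adjusted p = 0.195 with an estimated correlation) and oxidative phosphorylation (median 0.09, ATP5PF rose, adjusted p = 0.0269, and adjusted p = 0.355 with an estimated correlation). Adjusted over the list alone, 0 ER stress genes were called, 1 urea cycle gene rose, 1 stellate marker fell and 2 oxidative phosphorylation genes rose. PPARA differed from vehicle by 0.46 ± 0.20 (adjusted p = 0.388), CPT1A by 0.41 ± 0.39, PLIN2 by 0.24 ± 0.42, CAT by -0.55 ± 0.36 and GAPDH by -0.19 ± 0.21, none called. In all 51 probe sets were called, 40 rising for 30 genes and 11 falling for 9 genes, and 850 had an unadjusted p under 0.05. The count came down to 28 and 13 without 15-day vehicle replicates 1 and 2, and to 30, 20 and 25 without 150 mg/kg/day replicates 1, 2 and 4. With each array scaled to the same median 31 rose and 7 fell. In the 7 fits without 1 animal TK2 lost its call in all 7, FABP1, MAT1A and ATP5PF in 6 each, PSMB6 in 5, TIMP1 and PSMA3 in 4, ACADS in 3 and FADS2, MT1G and HADHB in 1 each. The calls of lists also ended for the stellate list without 15-day vehicle replicate 2 or 150 mg/kg/day replicate 2, the urea cycle list without 150 mg/kg/day replicate 1 and the oxidative phosphorylation list without 15-day vehicle replicate 3 or 150 mg/kg/day replicate 1 or 2.

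Of the 161 probe sets called at 400 mg/kg/day, 32 were also called at 150 mg/kg/day in the same direction, 23 rising and 9 falling, where 0.504 and 0.0964 would be shared by independent lists. At 150 mg/kg/day 157 of the 161 had the same sign as at 400, at 30 mg/kg/day 132 and at 3 mg/kg/day 113. All doses share the same 3 vehicle animals, which alone makes dose effects correlate and their signs agree. How many of the 161 would share a sign without any effect is not given here. The same-sign counts alone thus do not show a response at the lower doses. Across probe sets, which are not independent replicates, the effects of 400 and 150 mg/kg/day had a Pearson correlation of 0.606 against 0.571 for simulated groups with no effect. For 30 and 3 mg/kg/day the correlations were 0.462 and 0.403, against simulated values of 0.571 and 0.572. The simulation gave no group an effect. Effects present only at 400 mg/kg/day would lower a correlation but not a covariance. Correlations below the simulated values thus do not show that the lower doses acted otherwise than 400 mg/kg/day. The covariances with 400 mg/kg/day were 0.140, 0.102 and 0.0884 for 150, 30 and 3 mg/kg/day, against simulated values of 0.0801, 0.0802 and 0.0803. The shared count of 32 came down to 18 and 10 without 15-day vehicle replicates 1 and 2, and to 20, 13 and 17 without 150 mg/kg/day replicates 1, 2 and 4.

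In the 15-day animals on 30 mg/kg/day the transcription factor gene KLF11 was the only gene called, and it fell by 2.16 ± 0.32 (adjusted p = 0.00478). Its mean intensity in treated animals was 39.4, around the filter's limit. The other probe set for KLF11 differed by 0.74 (adjusted p = 0.497), so the fall was seen with 1 of 2 probe sets. Mitochondrial fatty acid oxidation had a median change of 0.51 with 0 of 17 genes called (adjusted p = 1.54e-08, but adjusted p = 0.215 with an estimated correlation), and 9 rose when adjusted over the list alone. PPAR-alpha targets (median 0.49), peroxisomal fatty acid oxidation (0.47) and ER stress (0.27) each had an adjusted p of 0.00873, and adjusted p = 0.215, 0.215 and 0.256 with an estimated correlation. Oxidative phosphorylation (median 0.18) had an adjusted p of 0.000645, immediate early genes (-0.35) of 0.0155 and the urea cycle (0.16) of 0.0381, and with an estimated correlation these were adjusted p = 0.256, 0.215 and 0.367. The call of KLF11 ended when only the compared groups were fitted (adjusted p = 0.152) and without 15-day vehicle replicate 3, which left 0 calls. Without 30 mg/kg/day replicates 3 and 4 there were 3 and 5 calls, and 4 lists were called without replicate 2. List calls ended without 15-day vehicle replicate 1 (PPAR-alpha targets, urea cycle), 2 (urea cycle) or 3 (immediate early genes), and without 30 mg/kg/day replicate 1 (ER stress), 2 (immediate early genes, peroxisomal oxidation, urea cycle) or 4 (urea cycle). In all 1 probe set was called by limma and 740 had an unadjusted p under 0.05.

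In the 15-day animals on 3 mg/kg/day limma called 0 probe sets, with 757 at an unadjusted p under 0.05. The ratio of 5' to 3' probe sets was 0.763 ± 0.182 (SD, n = 4) for ACTB and 1.32 ± 0.188 (SD, n = 4) for GAPDH, against 0.574 ± 0.033 and 1.06 ± 0.304 (SD, n = 3) in vehicle animals. Shifts of whole lists were present with the preset correlation only. ER stress and heat shock genes had a median of 0.41 (adjusted p = 1.71e-06, but adjusted p = 0.06 with an estimated correlation), mitochondrial fatty acid oxidation 0.34 (adjusted p = 0.000215, but adjusted p = 0.428 with an estimated correlation) and immediate early genes -0.43 (adjusted p = 0.00134, but adjusted p = 0.06 with an estimated correlation). Ribosomal proteins (median 0.14), the urea cycle (0.22) and oxidative phosphorylation (0.11) had adjusted p values of 0.00218, 0.00915 and 0.0141, and with an estimated correlation adjusted p = 0.444, 0.428 and 0.444. The count was 2 without 15-day vehicle replicate 1 or without 3 mg/kg/day replicate 3, and the oxidation list lost its call when the 2 arrays least like their groups were left out (adjusted p = 0.0575). List calls also ended without 15-day vehicle replicate 1 (urea cycle), 2 or 3 (ribosomal proteins) and without 3 mg/kg/day replicate 1 (ribosomal proteins, oxidative phosphorylation) or 4 (oxidative phosphorylation).

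Across the dose range at 15 days, FADS2 rose by 1.26 ± 0.14 per step (adjusted p = 5.85e-06), FABP1 by 0.89 ± 0.12, SCD by 0.84 ± 0.13, AKR1B10 by 0.84 ± 0.09 and NQO1 by 0.64 ± 0.06 (adjusted p = 1.76e-07). CYP2E1 fell by 0.85 ± 0.11 per step (adjusted p = 3.23e-05). The next largest falls were those of FGL1 (-0.70 ± 0.12), SPP2 (-0.68 ± 0.08), the apolipoprotein APOA4 (-0.66 ± 0.16) and CFHR4 (-0.60 ± 0.11). The slopes of FADS2, AKR1B10, SPP2 and APOA4 are not exact, as vehicle animals for the first pair and animals at 400 mg/kg/day for the others lay around the filter's limit. A slope also does not show an equal change at every step. FADS2 and SCD differed from 400 mg/kg/day by more at 3 mg/kg/day than in vehicle animals, so neither rose at the lowest step. Most of the fall of CYP2E1 lay between 150 and 400 mg/kg/day. Against vehicle, 0 probe sets were called at 3 mg/kg/day and 1 at 30 mg/kg/day. Mitochondrial fatty acid oxidation had 12 of 17 genes rising with dose (adjusted p = 2.71e-20, 0.00376 with an estimated correlation; 14 adjusted over the list alone). Fatty acid synthesis and PPAR-alpha targets had 6 each of 14 and 15 (adjusted p = 3.31e-09 and 1.76e-10, 0.000185 and 0.00133 with an estimated correlation; 7 and 9 adjusted over the list alone). Of 8 Kupffer cell and macrophage markers 2 fell with dose (adjusted p = 0.00748, but adjusted p = 0.0777 with an estimated correlation; 4 fell adjusted over the list alone). In all 234 probe sets were called, 135 rising for 100 genes and 99 falling for 75 genes, and 1051 had an unadjusted p under 0.05. With each array scaled to the same median 150 rose and 66 fell. APOA4 lost its call in 3 of the fits without 1 animal.

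After 4 days at 400 mg/kg/day FADS2 rose by 3.80 ± 0.83 (adjusted p = 0.0496), a call lost in most alternatives, and AKR1B10 by 3.10 ± 0.52 (adjusted p = 0.013), both with 1 vehicle animal below the filter's limit of 39.7. NQO1 rose 4.95-fold (2.31 ± 0.33, adjusted p = 0.00163). HADHB rose by 2.06 ± 0.39 and ACAA2 by 1.94 ± 0.27 (adjusted p = 0.00163). The 3 genes that fell were PZP (-3.64 ± 0.67), ITIH2 (-1.41 ± 0.30) and GNMT, which methylates glycine (-1.10 ± 0.22). With 2 animals in each group, 22 probe sets were called, 19 rising for 16 genes and 3 falling for 3 genes, and 575 had an unadjusted p under 0.05. With each array scaled to the same median 16 rose and 1 fell. The ratio of 5' to 3' ACTB probe sets was 0.868 ± 0.170 (SD, n = 2) in vehicle and 1.12 ± 0.133 (SD, n = 2) in treated animals.

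Mitochondrial fatty acid oxidation had 4 of 17 genes rising at 4 days and 13 not called (median 0.89, adjusted p = 4.38e-18, 0.00493 with an estimated correlation). The very long chain dehydrogenase ACADVL rose by 1.01 ± 0.21 and HADHA by 1.34 ± 0.28, and 11 rose when adjusted over the list alone. PPAR-alpha targets had 3 of 15 rising (median 0.88, adjusted p = 7.12e-11, 0.00217 with an estimated correlation; 9 adjusted over the list alone). FABP1 stood at 2.87 ± 0.70 (adjusted p = 0.0946) without a call. In the proteasome list PSMB7 rose by 1.21 ± 0.25 and 32 of 33 were not called (median 0.48, adjusted p = 1.86e-12, 0.00493 with an estimated correlation; 12 rose adjusted over the list alone). The other probe set for PSMB7 differed by 0.34 and was not called (limma adjusted p = 0.999). In oxidative phosphorylation COX5A rose by 1.56 ± 0.28 (median 0.34, adjusted p = 3.01e-10, 0.0267 with an estimated correlation; 4 rose and 1 fell adjusted over the list alone). Fatty acid synthesis had FADS2 rising (median 0.36, adjusted p = 5.27e-05, 0.00396 with an estimated correlation; 4 adjusted over the list alone). The oxidative stress list had NQO1, the peroxidase PRDX4 (1.08 ± 0.20) and TXN (1.20 ± 0.25) rising, with a median of 0.01 and a mean of 0.31 (adjusted p = 0.00083, 0.0465 with an estimated correlation; 5 rose adjusted over the list alone).

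Complement genes had a median of -0.42 at 4 days with 0 of 20 called (adjusted p = 1.43e-06, 0.0465 with an estimated correlation; 2 fell adjusted over the list alone). Another 7 lists were called with the preset correlation only. Xenobiotic metabolism (NQO1 rose, median 0.19) had an adjusted p of 0.00191, coagulation (0 of 28 called, median -0.23) of 0.00221 and acute phase proteins (ITIH2 fell, median -0.29) of 0.00256, and with an estimated correlation these were adjusted p = 0.0792, 0.156 and 0.156. ER stress (median 0.24) had 0.0159, red cell markers (-0.45) 0.0309, peroxisomal fatty acid oxidation (0.38) 0.0461 and immediate early genes (-0.24) 0.0498, each as an adjusted p with 0 genes called, and with an estimated correlation adjusted p = 0.181, 0.0792, 0.181 and 0.156. Red cell markers, which come from blood in the tissue, included HBB at -1.16 ± 0.54 and ALAS2 at -0.75 ± 0.22. PPARA (-0.41 ± 0.26), CPT1A (0.46 ± 0.51), PDK4 (0.86 ± 0.50), PLIN2 (1.69 ± 0.54), CAT (-0.50 ± 0.47), ACTB (0.33 ± 0.27) and GAPDH (-0.01 ± 0.28) were not called. Without vehicle replicate 1 or 2 there were 2 and 3 calls, and without 400 mg/kg/day replicate 1 or 2 there were 2 and 4. Of the genes named for 4 days, ACAA2 alone was called in every such fit. Fitting the 4 animals alone left 1 call, and array weights gave 113. FADS2 lost its call in 11 of 16 alternatives (adjusted p up to 0.687). The lists of ER stress, red cells, peroxisomal oxidation and immediate early genes each lost their call without vehicle replicate 1 and without 1 of the treated animals.

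The effects of 400 mg/kg/day at 4 and 15 days went the same way. Of the 161 probe sets called at 15 days, 151 (93.8%) had the same sign at 4 days. They included 90 of the 95 that rose and 61 of the 66 that fell, and 17 were called at both times. All 22 probe sets called at 4 days had the same sign at 15 days. Across all tested probe sets, which are not independent replicates, the Pearson correlation of the effects was 0.347 and the Spearman correlation 0.285, with no animals in common. For the probe sets called at 15 days the median ratio of the 4-day to the 15-day effect was 0.67. The test of the difference between the 15-day and the 4-day effect called 0 probe sets in limma, with 254 at an unadjusted p under 0.05, and 0 lists, so no gene was shown to respond differently with time. The Pearson correlation was 0.284 without 4-day vehicle replicate 1 and 0.282 without 4-day 400 mg/kg/day replicate 2.

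**Figure D3:**
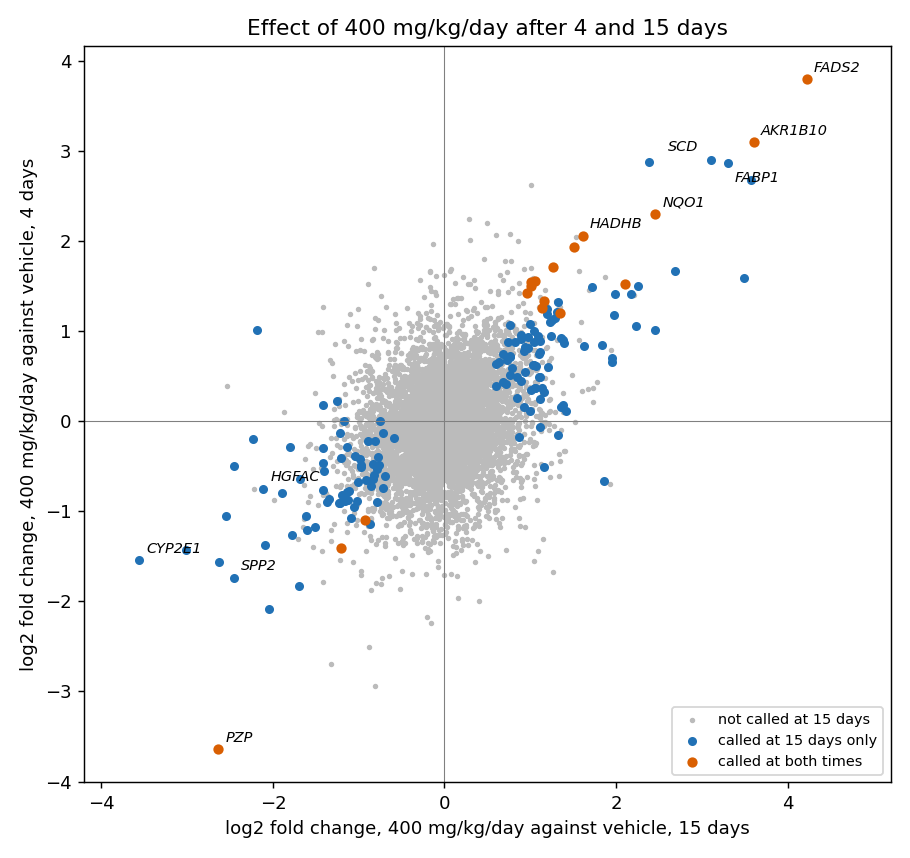
Log2 fold change of 400 mg/kg/day against vehicle at 15 days (x axis) and at 4 days (y axis) for 7535 probe sets. Orange points were called at both times (17), blue points at 15 days only and grey points not at 15 days; labels name genes of the report.

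The comparison of vehicle animals at 15 and 4 days does not separate time on study from differences between the arrays of those days. It had 65 probe sets called, 48 higher at 15 days for 38 genes and 17 lower for 11 genes, and 978 at an unadjusted p under 0.05. The genes named here were chosen after their values were seen. The transcription factor gene NFIX was higher at 15 days by 2.79 ± 0.48 (adjusted p = 0.00515), the protease FURIN by 1.95 ± 0.29 and MYC by 1.36 ± 0.24, and the apoptosis gene BAX was lower (-2.66 ± 0.37, adjusted p = 0.000772). The other probe sets for MYC differed by -0.71 to -0.32 and were not called. No gene list was called. Days coincided with a difference in the 5' to 3' ratio of ACTB, and the count came down to 13 and 10 without 4-day vehicle replicates 1 and 2, to 25 and 43 without 15-day vehicle replicates 1 and 2, to 1 when only the compared groups were fitted, and up to 262 with array weights.

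Comparing 400 with 3 mg/kg/day at 15 days, 4 animals each with no vehicle animals involved, called 315 probe sets, 145 higher at 400 mg/kg/day for 103 genes and 170 lower for 126 genes, and 1296 had an unadjusted p under 0.05. With each array scaled to the same median the balance turned, with 159 higher and 118 lower. FADS2 was higher at 400 mg/kg/day by 4.92 ± 0.59 (adjusted p = 1.91e-05), SCD by 3.95 ± 0.54, FABP1 by 3.28 ± 0.49, AKR1B10 by 2.85 ± 0.37 and ELOVL5 by 2.19 ± 0.24. CYP2E1 was lower (-3.88 ± 0.45, adjusted p = 1.48e-05), as were PZP (-2.92 ± 0.47), SPP2 (-2.68 ± 0.34), CFHR4 (-2.57 ± 0.47) and FGL1 (-2.43 ± 0.49). FADS2 lay below the filter's limit of 39.7 in all animals at 3 mg/kg/day (11.9 to 25.8), so its difference is set in part by the pseudocount, and those of SCD, SPP2 and APOA4 also involve a group around that limit. Of 14 fatty acid synthesis genes 5 were higher and 1 lower at 400 mg/kg/day (adjusted p = 1.53e-07, 0.000399 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). Of 15 PPAR-alpha targets 3 were higher (adjusted p = 3.5e-05, 0.038 with an estimated correlation; 7 adjusted over the list alone), among them VNN1 at 1.05 ± 0.29. Among apolipoproteins, APOB, the structural protein of very low density lipoproteins, was lower (-1.34 ± 0.24, adjusted p = 0.00151), as were APOA4 (-2.83 ± 0.66) and PLTP (-0.73 ± 0.15), while APOC1 was higher (0.90 ± 0.21). With the preset correlation 12 lists were called in all. With an estimated correlation 2 were called, those of fatty acid synthesis and PPAR-alpha targets. Mitochondrial fatty acid oxidation was thus not called with an estimated correlation in this comparison without vehicle animals. VNN1, APOA4 and APOC1 lost their calls in 5, 3 and 1 of the 8 fits without 1 animal.

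Comparing 400 with 150 mg/kg/day, 37 probe sets were called, 19 higher at 400 mg/kg/day for 9 genes and 18 lower for 10 genes, and 837 had an unadjusted p under 0.05. With each array scaled to the same median 19 were higher and 10 lower. The genes named here were chosen after their values were seen. The metallothioneins MT1G (-3.88 ± 0.46, adjusted p = 0.000171), MT1H (-1.26 ± 0.17) and MT1F (-0.94 ± 0.18) were lower at 400 than at 150 mg/kg/day, as were CYP2E1 (-2.56 ± 0.45), IGFALS (-1.54 ± 0.30), HGFAC (-0.99 ± 0.19) and PPARA (-0.87 ± 0.19, adjusted p = 0.0361). AKR1B10 (1.69 ± 0.37), ALDH1A1 (1.28 ± 0.24), ELOVL5 (1.27 ± 0.24) and TXN (0.87 ± 0.17) were higher. With the preset correlation 5 lists were called, and 0 with an estimated correlation. The count came down to 10, 4 and 18 without 150 mg/kg/day replicates 2, 3 and 4, to 11, 22 and 21 without 400 mg/kg/day replicates 1, 2 and 4, and to 6 when only the compared groups were fitted.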

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

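The patterns weighed here were picked after the results had been seen. What would speak for or against each explanation was written down before its test was run, except that the test of bright spike-ins was chosen after the first spike-in result and the test of other marker lists after the list results. In each group of 4 animals the gap between the most distant animal and its nearest neighbour was divided by the group's range, for genes on the log2 scale after the pseudocount, and compared with Dixon's critical value for 4 animals, which chance exceeds in about 1 of 20 groups. Of 141 such groups 9 lay above it, where chance gives 7.05. At 400 mg/kg/day and 15 days, replicate 4 was the lowest animal for FADS2 (647 against a next lowest of 1052.4, gap 0.898), ALDH1A1 (4538.4 against 7185.5, 0.908), HADHA (1003.1 against 1340.7, 0.841) and ITIH2 (939.8 against 1150.3, 0.998). In the same group replicate 1 was lowest for CYP2E1 (244.1 against 1544.8, 0.856) and CPT1A (129.7 against 169.3, 0.961), and replicate 2 for CFHR4 (22.8 against 126, 0.844). At 150 mg/kg/day replicate 1 was highest for TIMP1 (41.1 against 34.1, 0.855). At 30 mg/kg/day replicate 4 had the lowest mean correlation to its group (0.846 against 0.873, gap 0.872).

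More probe sets were called between 400 and 3 mg/kg/day (315) than between 400 mg/kg/day and vehicle (161), although vehicle should be the lower dose. The smaller number of vehicle animals does not account for this as a whole, since with 3 of the 4 animals at 3 mg/kg/day the count still had a median of 264.5 (242 to 282). The vehicle animal least like its group, replicate 1, does not account for it as a whole either, since without it 93 were called against 153 to 226 with 2 of the animals at 3 mg/kg/day. With array weights, which gave that animal 0.565, the counts came closer, 252 against vehicle and 334 against 3 mg/kg/day, so its spread may account for a part. A wider spread among vehicle animals in general and a response at 3 mg/kg/day opposite to that at 400 mg/kg/day stay open: across all probe sets the covariance of the effects of 400 and 3 mg/kg/day was 0.0884, not below the 0.0803 simulated without effects, but its spread was not estimated.

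The 65 probe sets called between vehicle animals at 15 and 4 days may come from arrays processed in separate batches or from time on study, and days and any such batches cannot be told apart in this design. Of 24 bacterial and phage spike-in probe sets, which no animal expresses, 5 differed between days by an exact permutation test without adjustment, with a median difference of 0.595 SD, but 15 of the 24 lay near the floor. Of the 9 spike-ins with a mean intensity over 100, 5 differed (4 after adjustment, smallest exact p = 0.000113), and all 9 were lower in the 4-day arrays (log2 -0.89 to -0.19, median 1.56 SD), which is consistent with separate processing. The day difference also appeared in the 400 mg/kg/day animals, with a correlation of 0.482 across probe sets and the same sign for 65 of 65 called probe sets, as both explanations predict. A comparison of each dose with vehicle of its own day does not cross this difference.

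The lists of endothelial, stellate and macrophage markers were lower at 400 mg/kg/day with the preset correlation, with TIMP1 the only member called, and the stellate and macrophage calls ended with an estimated correlation (adjusted p = 0.107 and 0.0949). A lower share of non-hepatocyte cells of every kind would lower the markers of bile duct, T and NK, B and plasma cells and neutrophils alike. Their pooled median log2 change was 0.0519 (95% bootstrap interval -0.27 to 0.35, 15 genes), against -0.42 for the first 3 lists (20 genes, 17 of them negative). A joint fall of those 15 genes was thus not shown, but the test cannot decide on the cell share. Its interval resampled genes and not animals, and the first 3 lists were picked because they were lower. The 15 genes also went both ways, from 0.95 for CAMP to -0.58 for IGKC, with 5 negative. A lower share of every kind, a change in those 3 cell types and a change in their expression of the markers stay open. The endothelial and macrophage calls depended on 15-day vehicle replicate 3 (adjusted p = 0.111 and 0.0887 without it).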

How the results depend on the processing

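The alternatives chosen after seeing the data were these: leaving out the arrays least like their groups (15-day vehicle replicate 1 and 30 mg/kg/day replicate 4), leaving out the 4-day arrays, and the lists with each array scaled to the same median. Among genes chosen by the naming rule, no call reversed in any alternative that tested the gene. Nor did a called list reverse in the alternatives that were run for lists. Other called genes were not checked for this. The counts of the dose slope and of 400 against 3 mg/kg/day stayed within 1.5 times the reported value in all alternatives. For the others the cause was not tested, except that fits with fewer arrays have less power by construction. A pseudocount of 64 gave 2 calls at 30 mg/kg/day and a correlation between days of 0.428. Without a filter there were 12 calls at 4 days, 24 for 400 against 150 mg/kg/day, 21 shared between doses and a correlation of 0.252. A filter at the 60th percentile gave 4 calls at 3 mg/kg/day and a correlation of 0.461, and quantile normalization 14 calls at 4 days and 3 lists at 3 mg/kg/day. Without a variance trend there were 28 calls at 150 mg/kg/day, 3 at 4 days, 39 between vehicle groups, 9 for 400 against 150 mg/kg/day and 19 shared. Array weights gave 252 calls at 400 mg/kg/day, 3 at 3 mg/kg/day, 113 at 4 days and 262 between vehicle groups. Fits of the compared groups alone gave 27 at 150 mg/kg/day, 1 at 4 days, 1 between vehicle groups and 6 for 400 against 150 mg/kg/day. With an estimated correlation 6 lists were called at 400 mg/kg/day, 7 at 4 days, 6 at 150 mg/kg/day, and 0 at 30 and 0 at 3 mg/kg/day. Without the arrays least like their groups there were 97 calls at 400 mg/kg/day, 32 at 150, 2 at 3 mg/kg/day and 20 shared, and without the 4-day arrays 2 at 30 mg/kg/day and 21 for 400 against 150 mg/kg/day.

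With a block for the replicate number there were 30 calls at 150 mg/kg/day, 4 at 30 mg/kg/day and 16 shared, and no other count moved by over 1.5 times. No pairing by number was seen in the values, though whether animals were matched across groups is not known. The 58 pairs of arrays with the same number had a mean correlation of -0.0023 after group means were removed, 0 of them over 0.1. For the 166 pairs with different numbers the mean was 0.00087, and 5 of 23 arrays correlated best with their own number.

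Leaving out 1 animal at a time gave 93 to 136 calls at 400 mg/kg/day and 15 days, 13 to 45 at 150, 0 to 5 at 30 and 0 to 2 at 3 mg/kg/day. It gave 2 to 4 at 4 days, where the remaining animal is assumed to vary like the other groups, 10 to 44 between vehicle groups and 4 to 28 for 400 against 150 mg/kg/day. For the slope it gave 167 to 265 and for 400 against 3 mg/kg/day 223 to 282. It gave 10 to 16 lists at 400 mg/kg/day and 15 days, 10 to 17 at 4 days, 9 to 13 at 150, 4 to 8 at 30 and 4 to 8 at 3 mg/kg/day. The difference between the 15-day and 4-day effects stayed at 0 calls. It gave 10 to 28 shared probe sets and a correlation between days of 0.282 to 0.339, all below the reported 0.347. The jackknife SE of 0.0625 treats the animals of all compared groups as 1 sample, so it is only a rough guide. Scaling to the same median raised the share of rising calls at 400 mg/kg/day from 59.0% to 73.2% and moved the median of all probe sets from -0.03 to 0.07. In the simulation of that comparison 2.99% of changes of 0.5 were recovered, so most changes of that size would be missed.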

Other observations

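Genes in this part were chosen after their values were seen. Some belong to the fixed lists, such as IGF1 and IGFBP2 to acute phase and other plasma proteins and BDH1 to ketone body metabolism. The fall of IGF1 is thus already part of a list result given above. Apart from the list of NRF2 targets, no pathway was tested in this part. After 15 days at 400 mg/kg/day IGF1, the circulating growth factor, changed by -1.41 ± 0.30 (adjusted p = 0.0106) and its carrier IGFBP3 by -0.78 ± 0.19 (adjusted p = 0.0305). The growth hormone receptor GHR stood at -0.63 ± 0.21 without a call (adjusted p = 0.148), and fell with dose by 0.17 ± 0.05 per step (adjusted p = 0.0462). Another IGF carrier, IGFBP2, went the other way without a call in either probe set (1.32 ± 0.53, adjusted p = 0.268, and 1.59 ± 0.58, adjusted p = 0.2). The sex hormone carrier SHBG, another plasma protein made by hepatocytes, changed by -0.87 ± 0.21 (adjusted p = 0.0265).

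Other single genes that fell at 400 mg/kg/day were fibronectin (FN1, -1.22 ± 0.23, adjusted p = 0.00415), the adhesion molecule VCAM1 (-1.23 ± 0.26, adjusted p = 0.00965) and the actin-binding TMSB4X (-0.78 ± 0.16, adjusted p = 0.00675). The matrix genes COL1A2 (-0.46 ± 0.34) and COL3A1 (-0.35 ± 0.37) were not called. Single genes that rose were the ketone body enzyme BDH1 (1.01 ± 0.23, adjusted p = 0.0148), the mitochondrial pyruvate carrier subunit MPC2 (1.03 ± 0.26, adjusted p = 0.0321) and the glycogen branching enzyme GBE1 (1.01 ± 0.21, adjusted p = 0.00833).

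The test of NRF2 targets was chosen after the rise of NQO1 and AKR1B10 had been seen. NQO1 and AKR1B10 are known targets of NRF2, a transcription factor of the oxidative stress response, and a candidate explanation for their rise is NRF2 activity. A list of 30 other NRF2 targets, 18 of them measured, was higher at 15 days (camera p = 0.00132, 0.0208 with an estimated correlation, median 0.40, 15 of 18 positive, 1 called) and at 4 days (p = 0.00198, 0.0251 with an estimated correlation, median 0.19, 13 of 18 positive, 0 called). Of the 18, 11 belong to other fixed lists whose results had been seen, so the test is not independent of them. The known targets HMOX1 (-1.10 ± 0.59), GSTP1 (-0.36 ± 0.26) and GCLM (0.01 ± 0.38) did not rise at 15 days, and NRF2 activity itself was not measured here.

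Other ways of grouping the same arrays served as a test of chance, written down after the counts were seen and before the regroupings were run. For 400 mg/kg/day against vehicle at 15 days 1 of 35 splits, the real one, gave as many as 161 calls. The highest other gave 22. The real grouping also gave the most calls for 150 mg/kg/day (51 against 9) and for 400 against 3 mg/kg/day (315 against 5). The same held for 400 against 150 mg/kg/day (37 against 1) and for the slope (234 against 2 in 100 regroupings). These counts argue against chance but do not exclude it. A share of 1 in 35 is the smallest that 35 splits allow, and it was not adjusted over the comparisons. Other splits also mix the compared groups, so a real difference widens their spread and lowers their counts. Chance cannot be excluded at 30 mg/kg/day either, where 13 of 35 splits gave as many as the real 1 and the highest other gave 5. At 3 mg/kg/day the real count was 0, so that all 35 splits had to give as many and this test says nothing (highest other 3).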
